A study of Rattus norvegicus with 6 samples.

How the data were processed

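Visium spatial gene expression for fresh frozen tissue was run by the authors on cryosections of treated rat tibialis anterior muscle, 4 sections at 2 weeks and 2 at 8 weeks, each labelled as a biological replicate. Muscles had been bisected at the middle of the defect before embedding. Per the file headers, Space Ranger 3.1.2 made the deposited files. The deposited matrices hold UMI counts per gene and barcode with no normalization, for every barcode of the capture area. The deposited tables of spatial enrichment hold Moran's I, a score per gene over spots under tissue, beside counts per gene, and the weights behind the score are not given in the sources used here. The authors' position tables give a tissue flag and a grid position for each barcode. The genome build and annotation are not given in the sources used here. Genes carry the Ensembl IDs and symbols of the files, of which 6079 of 25627 genes had no symbol of their own, and the reference table of gene names matched 0 of the Ensembl IDs and was not used.

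Spots under tissue with at least 100 UMIs entered the spot classes. The fibre share of a spot was the UMIs of a fixed list of 11 fibre genes found in the files over all UMIs except those of mitochondrially encoded genes, averaged over the spot and its neighbours on the hexagonal grid, up to 7 spots in all. The boundary of 12.9% was Otsu's threshold over all 6 sections with equal weight per section, and spots below it are called fibre-poor and the rest fibre-rich. Within fibre-rich spots, border spots lay at most 2 grid steps from a connected fibre-poor patch of at least 20 spots, and remote spots at least 5 steps from any. Spots were not assigned to cell types. UMI counts were summed per section over whole sections (all spots under tissue), spot classes or zones, so that each test has sections as its replicates.

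Genes were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM scaling and the quasi-likelihood test, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The comparisons of 8 with 2 weeks had batch and week as terms. Because both 8-week sections are in the shared batch, the week effect comes from that batch and the 2 earlier-batch sections inform the spread. Comparisons within sections had the section as a block, and the change of the class contrast between weeks was tested as an interaction that also allowed for batch. The fibre genes that set the classes stayed in library sizes but were left out of tests within sections. Fold changes are log2 of 8 over 2 weeks, fibre-poor over fibre-rich, or border over remote, with the standard error from the test statistic, and CPM values use TMM-scaled library sizes.

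A set of 42 gene lists with 604 entries was written from general knowledge, of which 558 entries had a symbol in the files and 46 were not analysed here. Lists with at least 3 tested members were tested with limma 3.58.1 camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Single values per section and Moran's I of each list (its median over members) were compared by exact permutation tests, two-sided, over all 15 splits, for which the smallest p is 0.0667. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule takes, per test, up to 10 passing genes with the largest rise and 10 with the largest fall, with a mean log2 CPM of at least 4 and no overlap between groups within the shared batch or the same sign in every section, without unnamed loci, mitochondrially encoded and ribosomal protein genes. It adds up to 4 members of each described list with a mean log2 CPM of at least 3, and where fewer than 5 genes pass it takes the 10 with the smallest p. A gene that met the rule is not reported here. Shares of counts have Wilson intervals at 95%, and a share of 0 is given with the share that 3 counts would make.

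The tests were tested on simulated data with changes planted in 200 genes of each comparison. Of planted changes of 1 on the log2 scale, 15.3% were recovered in whole sections (12196 genes), 5.10% in fibre-poor spots (11392 genes), 52.5% in fibre-rich spots (10362 genes), 82.1% between classes (11263 genes), 10.2% for the interaction (11422 genes) and 82.7% at the border (8281 genes). Of planted changes of 2, the shares were 80.8%, 62.6%, 95.0%, 100%, 66.0% and 99.0% in the same order, with 0 called in the wrong direction. Genes without a planted change made up 5 of 100, 6 of 73, 7 of 153, 7 of 178, 2 of 78 and 4 of 181 calls in that order. Simulated counts were drawn gene by gene from the fitted means and dispersion. Shifts between sections that many genes share, beyond the fitted terms, were therefore not simulated.

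The alternatives were no batch term, the shared batch alone, a block by replicate number, DESeq2 1.42.0, RLE scaling, no filter on low counts, mitochondrially encoded genes left out, a higher minimum of UMIs per spot, counts thinned to the shallowest library, another boundary or no averaging, spots near the boundary left out, other zone widths, every barcode in place of spots under tissue, and leaving out each section. An alternative using remote fibre-rich spots alone was added after the data were seen. Summaries and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Spots outside tissue were left out of the main tests, and histology images were not used here. In the tables of Moran's I filed under 2-week replicates 1 and 2, the counts per gene equal those of the other section's matrix for 100% of genes and those of their own for 3.01% and 3.12%, compared as whole numbers. They were kept as filed, which leaves the values per week as they are.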

Results

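Spatial transcriptomes were measured on 6 sections of rat tibialis anterior muscle, taken from Lewis rats (an inbred strain) after a volumetric muscle loss injury. The injury was a defect through the full thickness of the muscle that had been filled with a scaffold named Oligomer. There were 4 sections at 2 weeks and 2 sections at 8 weeks after treatment, each from a separate biological replicate. Visium captures polyadenylated RNA on a grid of barcoded spots, and each spot can cover several cells. The labels placed both 8-week sections and 2-week replicates 1 and 2 in a shared batch, and 2-week replicates 3 and 4 in an earlier batch. No untreated muscle and no defect without scaffold was part of the series, so the comparisons are between times and between regions of treated muscle.

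Depth differed between sections. The UMIs (unique molecular identifiers) on spots under tissue numbered 7238601 and 5589272 in 8-week replicates 1 and 2. They numbered 11411177, 14771750, 9464121 and 7554512 in 2-week replicates 1 to 4. The spots under tissue held a median of 1569 and 2396 UMIs at 8 weeks, and of 4276, 6862, 2894 and 3416 at 2 weeks in the same order. Mitochondrially encoded genes took 20.5% of the UMIs of 2-week replicate 1, against 10.7% and 11.9% at 8 weeks and 5.65%, 9.0% and 6.41% in the other 2-week sections. The 95% Wilson intervals of these shares were at most 0.0537 points wide and cover counting error only.

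How much of each section was muscle fibre was asked first, because a defect that fills with muscle or with other tissue changes every average over the section. Each spot was classed by the share of its UMIs from 11 abundant fibre genes, with a boundary at 12.9%. Fibre-poor spots, below the boundary, made up 64.0% ± 26.1 of spots at 2 weeks (SD, n = 4) and 11.9% ± 3.88 at 8 weeks (SD, n = 2), a difference of -52.0 points (exact permutation test, two-sided, p = 0.133). The smallest p that 15 splits of 4 against 2 sections allow is 0.0667. Within the shared batch the difference was -47.0 points (exact permutation p = 0.333), from 58.9% ± 40.7 (SD, n = 2). That p is the smallest that 6 splits of 2 against 2 sections allow. Single sections held 30.1%, 87.7%, 57.1% and 81.0% fibre-poor spots at 2 weeks, and 9.19% and 14.7% at 8 weeks, with 95% Wilson intervals at most 3.87 points wide. These intervals cover counting error only and treat spots as independent, though each class rests on a mean over neighbouring spots. The share was higher in 4 of 4 sections at 2 weeks than in either section at 8 weeks.

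**Figure D1:**
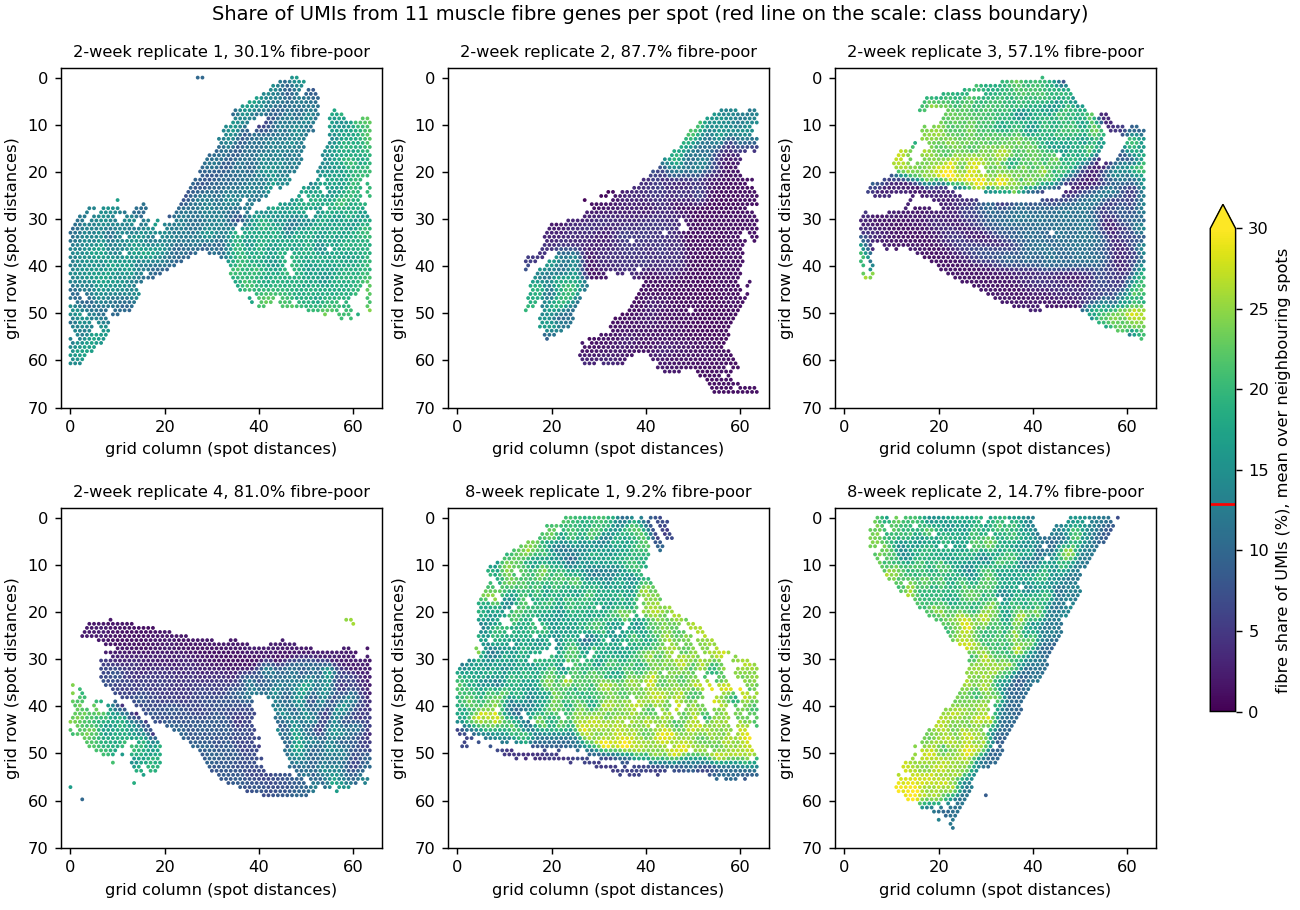
Each panel maps the fibre share of UMIs in percent (colour) over the spots of a section, with both axes in spot distances and the class boundary of 12.9% as a red line on the colour scale. Fibre-poor spots cover 87.7% of 2-week replicate 2 and 9.19% of 8-week replicate 1.

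2-week replicate 1 stood apart from the other 2-week sections in this measure. None of its 2156 spots had a fibre share under 5%, a limit chosen after the maps were seen (0 of 2156 spots, which allows a share of up to 0.139%), and 54.8% of its spots lay within 25% of the boundary on either side. In 2-week replicates 2, 3 and 4 the spots under that share made up 76.2%, 26.1% and 26.2%. Its fibre-poor spots were shallower than its fibre-rich spots, with a median of 1587 against 5094 UMIs, as they were in 2-week replicate 2 (6523 against 9457 UMIs). The fibre-poor spots were deeper in 2-week replicates 3 and 4 (3386.5 against 2623 and 3556 against 3173 UMIs) and at 8 weeks (7625 against 1436 UMIs in replicate 1 and 4860 against 2105.5 in replicate 2).

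Across whole sections, the comparison of 8 with 2 weeks asked which transcripts the treated muscle gained or lost with time. Actc1 (ENSRNOG00000008536), the cardiac actin isoform that developing and regenerating skeletal fibres also use, fell 19-fold, from 537 ± 288 CPM (counts scaled to a common library size; SD, n = 4) to 37.7 ± 0.19 CPM (SD, n = 2). Its log2 fold change was -4.25 ± 0.44 (SE), with an adjusted p = 0.0453. Mki67, carried by cycling cells, fell from 15 ± 1.35 to 2.37 ± 0.39 CPM, and Cidec, a lipid droplet protein of fat cells, rose from 1.76 ± 2.02 to 30.4 ± 12.4 CPM. Fold changes here and in both spot classes come from the shared batch, because the batch was a term of the fit, whereas the means in CPM cover all 4 sections at 2 weeks and both at 8 weeks.

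Of 12407 genes tested in whole sections, 12 passed, 4 higher and 8 lower at 8 weeks. Besides Actc1 and Mki67, the genes that fell were C1qtnf3, a secreted protein of the C1q family (53.1 to 2.02 CPM), Klk1, a tissue kallikrein whose close paralogs were not separated here (158 to 15.6 CPM), and Capn6, a calpain without protease activity (61.5 to 4.18 CPM). The imprinted growth regulators Cdkn1c and Plagl1 fell by 2.32 and 2.27 on the log2 scale. The remaining passing genes were named after their values were seen. Adamts17, a secreted metalloprotease, had a log2 fold change of -4.68, and Agt (angiotensinogen), Adamtsl3 and Ubxn10 had log2 fold changes of 3.75, 2.45 and 5.19. Cidec and Ubxn10 were near 1 UMI in 2-week replicate 1, so their fitted folds depend on the prior count.

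Among the fixed gene lists in whole sections, the myogenic and embryonic fibre list had 16 tested members, of which 1 fell and 15 did not pass, while 12 fell when adjusted over the list alone. Its median log2 fold change was -2.36 (camera adjusted p = 1.09e-07, adjusted p = 0.754 with an estimated correlation). The cell cycle list had 1 of 19 members fall, 16 when adjusted over the list alone, with a median of -1.65 (camera adjusted p = 1.98e-12, adjusted p = 0.686 with an estimated correlation). In the adipocyte list 1 of 13 members rose, 8 when adjusted over the list alone, and the median was 1.84 (camera adjusted p = 6.65e-10, adjusted p = 0.671 with an estimated correlation). No member of the fibrillar collagen list passed, 3 of 22 fell when adjusted over the list alone, and its median was -1.08 (camera adjusted p = 0.00158, adjusted p = 0.822 with an estimated correlation). The adult fast fibre, glycolysis and oxidative phosphorylation lists had medians of 0.92, 1.06 and 0.62 with 0 members passing, alone or over all genes, and 11, 12 and 20 members higher at 8 weeks. Their camera adjusted p were 0.000199, 5.07e-05 and 4.10e-05, and the adjusted p = 0.822 with an estimated correlation in each. These fibre lists moved with the share of fibre-poor spots, which was 64.0% at 2 weeks and 11.9% at 8 weeks. Of 42 lists, 18 passed camera with its preset correlation, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05.

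The whole-section count rested on few sections. Within the shared batch alone 0 genes passed by edgeR (1351 at an unadjusted p under 0.05), and DESeq2 called 358 with all sections. Without 2-week replicate 1 the count was 2313 and without 2-week replicate 2 it was 481, while it was 0 without 8-week replicate 1, 8-week replicate 2, 2-week replicate 3 or 2-week replicate 4 (1118, 865, 1401 and 1427 genes at an unadjusted p under 0.05).

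The comparison in fibre-poor spots asked how tissue with a low share of the 11 fibre genes changed with time, though fibre content within this class also differed between the weeks. In 2-week replicate 1, only 87 of 649 fibre-poor spots remained with spots near the boundary left out. There the median log2 ratio of fibre-poor to fibre-rich spots was 0.44 for the myogenic and embryonic list. For the denervation and atrophy list it was 0.52, and both ratios were negative in every other section. Single genes of fat cells were among those that rose, and single genes of activated fibroblasts among those that fell. Adipoq, the fat hormone adiponectin, rose from 10.5 ± 10.9 CPM (SD, n = 4) to 227 ± 42.5 CPM (SD, n = 2), with an adjusted p = 0.0284. Cidec rose from 2.42 ± 2.59 to 60.1 ± 7.92 CPM (log2 fold change 7.0 ± 0.48 (SE), adjusted p = 0.00466). Cthrc1, secreted by activated fibroblasts, fell 9.52-fold from 728 ± 369 to 51.4 ± 13.8 CPM (adjusted p = 0.0422). Lrrc15, a surface protein of fibroblasts exposed to TGF-beta, fell 16.4-fold from 332 ± 147 to 16.4 ± 4.23 CPM (adjusted p = 0.0313).

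Of 11637 genes tested in fibre-poor spots, 48 passed, 27 higher and 21 lower at 8 weeks. The other largest rises were Retn, the fat hormone resistin (4.13 to 82.9 CPM), Thrsp, a regulator of fat synthesis (14.4 to 154 CPM), Agt (2.1 to 56.3 CPM), Cdo1, which breaks down cysteine (10.9 to 77.9 CPM), and Spock2, a matrix proteoglycan (7.54 to 56.4 CPM). Retsat, a retinol saturase, rose from 119.6 to 769 CPM, Sncg, a synuclein, from 83.3 to 507 CPM, and Ppp1r3c, a glycogen regulator, from 22.7 to 113 CPM. Dlk1, an imprinted protein that holds back fat cell formation and is made by developing muscle, had the lowest log2 fold change of the passing genes (-7.41 ± 1.01 (SE), 287 to 2.44 CPM, adjusted p = 0.0351). Actc1 fell from 647 to 32.4 CPM, and 2-week replicate 1 stood apart in it with 1294 CPM, as it did in the share of mitochondrial UMIs in fibre-poor spots, 10.5% against 4.40% to 5.37% in the other 2-week sections. Falls were also found in Adamts17 (28.8 to 0.746 CPM), Klk1 (225 to 14.4 CPM), C1qtnf3 (76.8 to 2.54 CPM), Capn6 (84.1 to 3.42 CPM), the transcription factor Sox4 (22.5 to 1.97 CPM) and the metalloprotease Adam12 (129.6 to 4.94 CPM). Adipoq and Retn had 0 UMIs in the fibre-poor spots of 2-week replicate 1, Cidec stood at 0.379 and 0.462 CPM in those of 2-week replicates 1 and 2, and the counts of Dlk1 and Adamts17 were near 0 at 8 weeks, so their fitted folds depend on the prior count.

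In the adipocyte list 6 of 13 members rose in fibre-poor spots and 7 did not pass, and 12 rose when adjusted over the list alone (median log2 fold change 2.65, camera adjusted p = 6.12e-14, adjusted p = 0.226 with an estimated correlation). The myogenic and embryonic list had 2 of 16 members fall, Dlk1 and Actc1, and 13 when adjusted over the list alone (median -2.89, camera adjusted p = 4.19e-09, adjusted p = 0.739 with an estimated correlation). In the cell cycle list Mki67 fell (18.3 to 2.64 CPM) and 18 of 19 members did not pass, and 6 fell when adjusted over the list alone (camera adjusted p = 3.75e-08, adjusted p = 0.739 with an estimated correlation). Vwf, a clotting factor stored by endothelium, rose from 50.3 to 212 CPM as 1 of 13 endothelial members, 2 when adjusted over the list alone (camera adjusted p = 0.000531, adjusted p = 0.739 with an estimated correlation). Of 14 myofibroblast members 2 fell, Cthrc1 and Tgfb3 (56.1 to 14.9 CPM), also 2 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.568). Mmp14, a membrane collagenase (57.9 to 10 CPM), was the 1 of 14 matrix degradation members that fell, 3 when adjusted over the list alone (camera adjusted p = 0.0577). Smoc2 (114 to 32.5 CPM) was the 1 of 14 fibroblast and progenitor members that fell, with 2 falling and 1 rising when adjusted over the list alone, and that list did not pass either (camera adjusted p = 0.568). None of 22 fibrillar collagen members passed, and 4 fell when adjusted over the list alone (median -0.74, camera adjusted p = 0.00866, adjusted p = 0.739 with an estimated correlation). The Schwann cell list had 6 of 10 members rise when adjusted over the list alone and 0 over all genes (camera adjusted p = 0.00976, adjusted p = 0.739 with an estimated correlation). Fibre genes were higher at 8 weeks inside this class, with medians of 0.72 for the genes that set the classes, 0.68 for the adult fast fibre list and 0.89 for the glycolysis list and 0 members passing, over all genes or alone. Their camera adjusted p were 0.00269, 0.0101 and 0.000114, and the adjusted p = 0.739 with an estimated correlation in each. These p do not allow for the choice of spots by fibre share, which was made with the genes of the first list. At 8 weeks 14 of 2763 and 0 of 1859 spots in replicates 1 and 2 had a fibre share under 5%, against 1476 of 1937, 663 of 2536 and 488 of 1864 in 2-week replicates 2 to 4 and 0 of 2156 in 2-week replicate 1, so the class did not hold like tissue at both times.

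Within the shared batch alone 35 genes passed in fibre-poor spots. The count was 562 without 2-week replicate 1, 596 without 2-week replicate 2, and 0 without 8-week replicate 1, without 8-week replicate 2 or with the boundary set in each section (1400, 1067 and 1778 genes at an unadjusted p under 0.05 by edgeR), and DESeq2 called 332 with all sections.

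**Figure D2:**
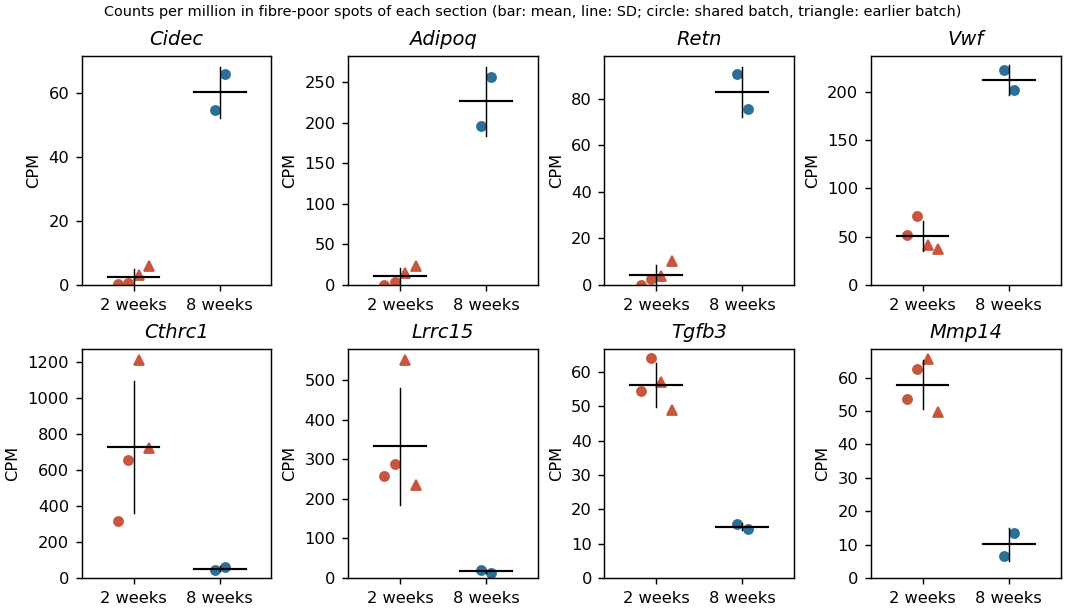
CPM of 8 genes in the fibre-poor spots of each section at 2 and 8 weeks, with a point per section, a bar for the mean and a line for the SD. Adipoq was at most 23.8 CPM in the 2-week sections and at least 196 CPM in the 8-week sections.

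In fibre-rich spots, the comparison asked what changed in tissue with more muscle fibres. Contractile genes of immature fibres, myosins included, were among those that fell. Myh8 (ENSRNOG00000068010), the neonatal myosin heavy chain, fell 24.5-fold from 191 ± 93.5 CPM (SD, n = 4) to 11 ± 1.62 CPM (SD, n = 2), with a log2 fold change of -4.62 ± 0.29 (SE) and an adjusted p = 0.000173. Myh3, the embryonic myosin heavy chain, fell 7.78-fold from 275 ± 106 to 46.5 ± 11.4 CPM (adjusted p = 0.000975). Actc1 fell 20.4-fold from 538 ± 237 to 36.4 ± 4.96 CPM (adjusted p = 0.000148). Gsn, the actin-severing protein gelsolin that fibroblasts also carry, rose 8.25-fold from 583 ± 88.2 to 4881 ± 963 CPM (adjusted p = 0.00297).

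Of 10617 genes tested in fibre-rich spots, 428 passed, 240 higher and 188 lower at 8 weeks. The myogenic and embryonic list had 10 of 16 members fall and 6 not pass, and 14 fell when adjusted over the list alone (median log2 fold change -2.30, camera adjusted p = 3.20e-12, adjusted p = 0.685 with an estimated correlation). Besides the myosins and Actc1, Tnnt2, a troponin T of heart and immature muscle, fell from 92.4 to 12.2 CPM, Mymk, which drives fusion of muscle precursors, from 35.8 to 5.51 CPM, and Dlk1 from 389 to 3.29 CPM. Myog, a transcription factor of differentiating muscle cells, fell from 62.3 to 26.4 CPM, and the growth factor Igf2 from 728 to 101 CPM. The cell cycle list had 8 of 19 members fall, 17 when adjusted over the list alone (median -2.15, camera adjusted p = 4.60e-14, adjusted p = 0.124 with an estimated correlation), Mki67 among them (12.3 to 2.02 CPM). Klk1 fell from 103 to 14.5 CPM, Adam12 from 28.2 to 1.69 CPM, and Tnn, a tenascin of the matrix, from 61.1 to 1.2 CPM. Cox7a1, the muscle form of a respiratory chain subunit, rose from 27.9 to 58.2 CPM as 1 of 20 oxidative phosphorylation members, also 1 when adjusted over the list alone (camera adjusted p = 0.000637, adjusted p = 0.685 with an estimated correlation). Of 14 members of the unfolded protein response list, 3 fell, Pdia4, Hsp90b1 and Hspa5, chaperones of the secretory pathway, with 5 falling when adjusted over the list alone (camera adjusted p = 0.0453, adjusted p = 0.685 with an estimated correlation). Fibre genes were higher at 8 weeks in this class too, with medians of 0.44 for the genes that set the classes (0 members passing, 1 rising when adjusted over the list alone), 0.58 for the adult fast fibre list and 0.71 for the glycolysis list (0 members passing in either, over all genes or alone). Their camera adjusted p were 0.00348, 0.0174 and 0.00236, and the adjusted p = 0.685 with an estimated correlation in each. As in fibre-poor spots, these p do not allow for the choice of spots by fibre share.

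**Figure D3:**
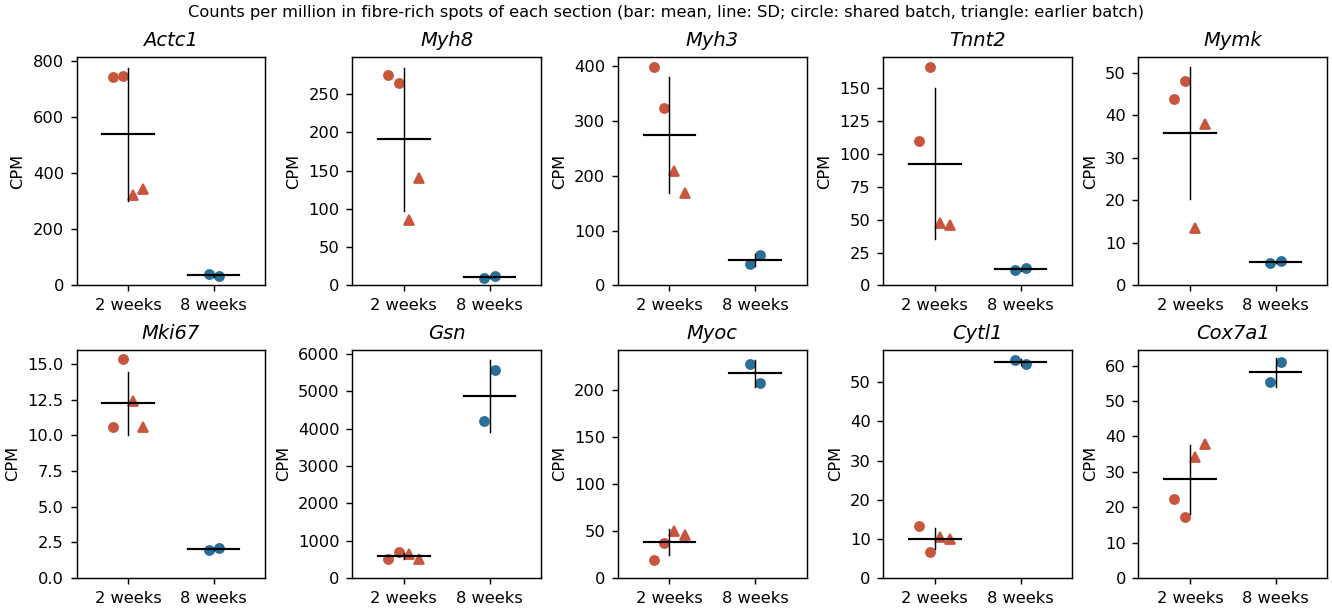
CPM of 10 genes in the fibre-rich spots of each section at 2 and 8 weeks, with a point per section, a bar for the mean and a line for the SD. Myh8 was 9.87 and 12.2 CPM in the 8-week sections, and Gsn was 4201 and 5562 CPM.

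Matrix genes and markers of non-muscle cells moved in both directions within fibre-rich spots. In the fibrillar collagen list 3 of 22 members fell, Postn (periostin, 1403 to 279 CPM) among them, with 7 falling and 1 rising when adjusted over the list alone (camera adjusted p = 0.00236, adjusted p = 0.685 with an estimated correlation). The basement membrane list had 2 of 12 members fall, Col4a2 (191 to 67.9 CPM) and Nid2, and 6 when adjusted over the list alone (camera adjusted p = 0.00337, adjusted p = 0.685 with an estimated correlation). Cthrc1 fell from 166 to 18.3 CPM and Ccn2, a matricellular growth factor, rose from 61.4 to 232 CPM, in a myofibroblast list that did not pass (1 rose and 1 fell of 14, 1 rose and 2 fell when adjusted over the list alone, camera adjusted p = 0.794). Of 13 fibroblast and progenitor members 4 rose and 1 fell, 7 and 2 when adjusted over the list alone (camera adjusted p = 0.0113, adjusted p = 0.685 with an estimated correlation), with Gsn and Pi16 (26.5 to 85.4 CPM) rising and Smoc2 (73.2 to 31.2 CPM) falling. The tenocyte list had 4 of 11 members rise, 7 when adjusted over the list alone (camera adjusted p = 0.000503, adjusted p = 0.685 with an estimated correlation). Its members Comp, Chad and Cilp2 had means of 19.9 to 39.3, 5.89 to 22.6 and 36.8 to 93.1 CPM. In Comp, the earlier-batch sections at 2 weeks held 25.2 and 43.3 CPM, close to the 28.4 and 50.2 CPM at 8 weeks, so its rise was within the shared batch. Ostn, a secreted muscle peptide, likewise had 49.4 CPM in 2-week replicate 3 against 65.1 and 62.9 CPM at 8 weeks.

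The adipocyte list had 5 of 11 members rise in fibre-rich spots, 6 when adjusted over the list alone (camera adjusted p = 0.000241, adjusted p = 0.685 with an estimated correlation). Adipoq rose from 1.77 ± 1.94 to 73.8 ± 64.2 CPM and Cfd, the complement protease adipsin, from 107 to 411 CPM. The calcium-binding protein S100b also rose (11 to 40.4 CPM). Its value was low in 2-week replicate 1, at 5.96 CPM. Rises were also found in Myoc (myocilin, 38.4 to 218 CPM), the adhesion protein Cadm3 (10.5 to 62.3 CPM) and the secreted protein Cytl1 (10.1 to 55.1 CPM). Among other markers, the mast cell proteases Cpa3 (25.2 to 14 CPM) and Cma1 (61.9 to 40.5 CPM) fell, as 2 of 4 members of that list, and 2 of 10 hypoxia members rose, Ndrg1 and Egln3. Neither the mast cell list (camera adjusted p = 0.155) nor the hypoxia list with an estimated correlation (adjusted p = 0.685 with an estimated correlation, camera adjusted p = 0.0198) passed.

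Within the shared batch alone 547 genes passed in fibre-rich spots. The count was 100 without 8-week replicate 1 and 76 without 8-week replicate 2, and 72 with the boundary set in each section. 2-week replicate 2 gave only 238 fibre-rich spots.

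Fibre-poor and fibre-rich spots of the same section were compared to ask what the fibre-poor tissue was made of. Collagens rose in fibre-poor spots and genes of energy metabolism fell. Col1a1, the main chain of type I collagen, rose from 7506 ± 2872 to 22385 ± 8591 CPM (SD, n = 6), with a log2 fold change of 1.57 ± 0.17 (SE) and an adjusted p = 2.00e-05, and was higher in 6 of 6 sections. Comp, a cartilage and tendon matrix protein, rose from 31.6 ± 22.4 to 135 ± 112 CPM in 6 of 6 sections (adjusted p = 1.13e-05). Ckmt2, the mitochondrial creatine kinase of muscle, fell from 1902 ± 938 to 425 ± 365 CPM and was lower in 6 of 6 sections (adjusted p = 1.74e-05). The fibre genes that set the classes were left out of this test. UMIs of other genes, collagens included but not mitochondrially encoded ones, count against the fibre share of a spot. The p of this comparison do not allow for that choice of spots, for rises as for falls.

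Of 11642 genes tested, 4952 passed between the classes, 2472 higher and 2480 lower in fibre-poor spots. In the fibrillar collagen list 22 of 22 members rose, over all genes and when adjusted over the list alone (camera adjusted p = 1.43e-11, adjusted p = 0.344 with an estimated correlation), with Col1a2 (4788 to 14101 CPM), Thbs2 (126 to 393 CPM) and Fmod (130.4 to 446 CPM) among those furthest up. The collagen crosslinking list had 12 of 13 members rise, the same number when adjusted over the list alone (camera adjusted p = 4.93e-06, adjusted p = 0.344 with an estimated correlation), and the matrix degradation list 11 of 15, again the same alone (camera adjusted p = 3.28e-05, adjusted p = 0.344 with an estimated correlation). Mmp12, the macrophage elastase (7.06 to 29.7 CPM), Mmp9 (4.71 to 21.6 CPM) and Mmp14 (9.43 to 34.6 CPM) were among them. The tenocyte list had 10 of 12 members rise, 10 alone (camera adjusted p = 4.61e-05, adjusted p = 0.344 with an estimated correlation), with the tendon protein Tnmd (49.3 to 191 CPM) and Cilp2 (66.9 to 221 CPM). The myofibroblast list had 12 of 14 members rise, 13 when adjusted over the list alone (camera adjusted p = 5.14e-05, adjusted p = 0.344 with an estimated correlation), with Cthrc1 (140.2 to 413 CPM) and Tgfbi (269 to 657 CPM). Lrrc15 (42.4 to 187 CPM), Hhipl1, Megf6 and Ccn5 completed the largest rises, with log2 fold changes of 1.92, 1.98, 1.82 and 1.71, in 6 of 6 sections each.

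Some immune lists were higher in fibre-poor spots as well, while the interferon, mast cell and neutrophil lists did not pass (camera adjusted p = 0.167, 0.567 and 0.874). Of 16 macrophage members 15 rose, 15 also when adjusted over the list alone (camera adjusted p = 2.69e-06, adjusted p = 0.344 with an estimated correlation), with Lyz2, lysozyme (363 to 684 CPM), Cd14 (19 to 38.6 CPM) and the mannose receptor Mrc1 (56.1 to 106 CPM). The lipid and foreign-body macrophage list had 11 of 12 members rise, 11 alone (camera adjusted p = 6.70e-06, adjusted p = 0.344 with an estimated correlation), with Spp1 (osteopontin, 15.7 to 39.5 CPM, 5 of 6 sections) and Lgals3 (galectin 3, 191 to 423 CPM). The complement list had 10 of 12 rise, 10 alone, the antigen presentation list 8 of 13, 8 alone, and the lysosome list 13 of 17, 13 alone. Their camera adjusted p were 6.42e-05, 0.000169 and 4.61e-05, and the adjusted p = 0.349 with an estimated correlation at most. C4b and C4a, which are close paralogs, rose from 167 to 514 and 61 to 166 CPM, and Cd74, a chaperone of antigen presentation, from 543 to 991 CPM. In the endothelial list 2 of 13 members rose and 1 fell, with 1 and 1 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.638). Plvap, a protein of fenestrated vessels, rose from 102 to 259 CPM in 6 of 6 sections.

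Metabolic and fibre lists fell in fibre-poor spots, which were themselves chosen by a low share of fibre transcripts. As for the lists that rose, their p do not allow for that choice. The oxidative phosphorylation list had 20 of 20 members fall, the glycolysis list 12 of 12, the fatty acid oxidation list 13 of 13, the mitochondrially encoded list 13 of 13 and the adult fast fibre list 11 of 11, in each also when adjusted over the list alone. Their camera adjusted p were 7.20e-13, 2.45e-08, 5.11e-08, 3.43e-11 and 3.75e-07, and the adjusted p = 0.344 with an estimated correlation in each. Cycs, cytochrome c, fell from 220.3 to 41.1 CPM, and Fbp2, the muscle form of a gluconeogenic enzyme, from 43.2 to 8.18 CPM. The membrane proteins Scn4b (139.9 to 30.8 CPM), Ca14 (75.2 to 16.7 CPM), Aqp4 (27 to 6.72 CPM) and Slc38a3 (29 to 6.54 CPM) fell in 6 of 6 sections, as did Ky (47.9 to 9.78 CPM), Smco1 (28.6 to 6.04 CPM) and Ostn (40.9 to 10.2 CPM). The myogenic and embryonic list had 6 of 16 members fall, 6 alone, Myf6 (141 to 60.6 CPM) and Cdh15 (24.8 to 12.9 CPM) among them (camera adjusted p = 0.0143, adjusted p = 0.672 with an estimated correlation). The shared batch alone gave 3456 genes.

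Whether this contrast differed between the weeks was tested as an interaction. No gene passed of 11642 by edgeR (0, with 638 at an unadjusted p under 0.05), and DESeq2 also called 0. The named genes among the 10 with the smallest p are given as not passing, each with an adjusted p = 0.897. For Fbln7, a matrix protein of the fibulin family, the log2 ratio of fibre-poor to fibre-rich spots was 1.62 ± 0.16 at 2 weeks (SD, n = 4) and 0.06 ± 0.03 at 8 weeks (SD, n = 2). For Svep1, a large adhesion protein, it was -0.34 ± 0.27 and 0.95 ± 0.01. For Map1lc3b, an autophagy protein, it was -0.01 ± 0.38 and -1.44 ± 0.28, and for Chrne, the adult acetylcholine receptor subunit, 0.11 ± 0.61 and -1.23 ± 0.44. Selenoh and Polr2k had interaction log2 fold changes of -2.60 and -2.38, and Cesl1, a member of a family of close paralogs, of 3.49. Without 2-week replicate 1 there were 25 passing genes and without 2-week replicate 2 there were 162.

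Fibre-rich spots at the border of fibre-poor patches were compared with remote fibre-rich spots of the same section, to ask how muscle next to the patches differed. Slow and metabolic genes were among those that fell at the border, and genes of denervated or regenerating fibres among those that rose. Myh7, the slow myosin heavy chain, fell from 793 ± 432 to 181 ± 123 CPM (SD, n = 6) and was lower in 6 of 6 sections (log2 fold change -2.16 ± 0.26 (SE), adjusted p = 0.000112). Sln, sarcolipin, an inhibitor of the calcium pump, rose from 85.1 ± 64.9 to 346 ± 308 CPM in 6 of 6 sections (log2 fold change 1.80 ± 0.34 (SE), adjusted p = 0.00279). Chrna1, the acetylcholine receptor subunit that spreads over denervated fibres, rose from 28.9 ± 31.5 to 105 ± 89.1 CPM in 6 of 6 sections (adjusted p = 0.00279). The fibre genes that set the classes were lower too at the border, with a median log2 fold change of -0.52 that was not tested, since they define the classes. Border spots were chosen by closeness to spots of low fibre share. The p of this comparison do not allow for that choice, for falls as for rises.

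Of 8505 genes tested, 859 passed at the border, 356 higher and 503 lower. The oxidative phosphorylation list had 19 of 20 members fall, 19 when adjusted over the list alone (median log2 fold change -0.75, camera adjusted p = 8.89e-15, adjusted p = 0.237 with an estimated correlation), and Ndufs1, a subunit of complex I, fell from 303 to 143 CPM. The mitochondrially encoded list had 12 of 12 fall, 12 alone (median -1.23, camera adjusted p = 2.32e-14), the fatty acid oxidation list 12 of 13, 12 alone (camera adjusted p = 2.69e-10), and the glycolysis list 10 of 11, 11 alone (camera adjusted p = 1.83e-10). The adjusted p = 0.237 with an estimated correlation in each of these lists. Slc2a4, the insulin-responsive glucose transporter, fell from 319.6 to 157 CPM, Slc16a3, a lactate transporter, from 165 to 66.9 CPM, and Fbp2 from 49.5 to 17 CPM. The slow fibre list had 5 of 11 members fall, 8 when adjusted over the list alone, and the adult fast fibre list 4 of 10, 8 alone. Their medians were -0.59 and -0.49 (camera adjusted p = 4.77e-05 and 3.05e-06, adjusted p = 0.296 and 0.237 with an estimated correlation). Myl3, a slow myosin light chain, fell from 1239 to 411 CPM, Tfrc, the transferrin receptor, from 97.8 to 37.6 CPM, Lmcd1 from 99.8 to 39.4 CPM, and Ostn from 44.7 to 15.4 CPM. Rxrg, Rtn4ip1 and Trpt1 had log2 fold changes of -1.15, -1.15 and -1.12.

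**Figure D4:**
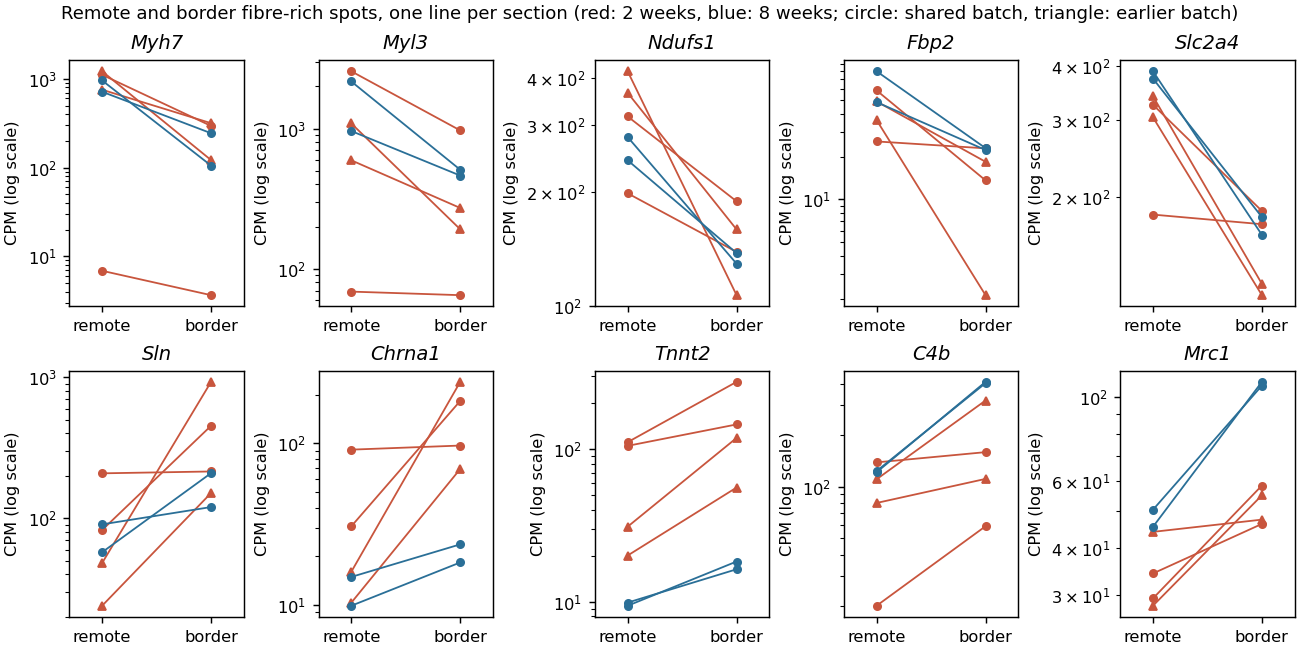
CPM on a log scale of 10 genes in remote and border fibre-rich spots, with a line joining the pair of values of each section. Myh7 was lower and Sln higher at the border in 6 of 6 sections.

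The denervation and atrophy list had 8 of 11 members rise at the border, 8 when adjusted over the list alone (camera adjusted p = 1.90e-05, adjusted p = 0.237 with an estimated correlation), with the transcription factors Runx1 (5.07 to 17 CPM) and Myog (40.1 to 77.3 CPM, 5 of 6 sections) besides Sln and Chrna1. The myogenic and embryonic list had 8 of 16 members rise, 11 alone (camera adjusted p = 2.59e-06, adjusted p = 0.298 with an estimated correlation), including Tnnt2 (47.7 to 105 CPM) and the fusion peptide Mymx (10.9 to 25.2 CPM, 5 of 6 sections). Chrna1 and Myog stand in both lists. Macrophage markers were higher at the border too, with a list median log2 ratio of 0.34 ± 0.25 at 2 weeks (SD, n = 4) and 1.04 ± 0.06 at 8 weeks (SD, n = 2), a difference that was not tested, against 0.96 ± 0.92 and 0.18 ± 0.17 for the myogenic list. Of 16 members 12 rose, 14 when adjusted over the list alone (camera adjusted p = 7.90e-08, adjusted p = 0.237 with an estimated correlation), with Mrc1 (38.7 to 70.7 CPM) and Adgre1 (13.5 to 25.2 CPM) in 6 of 6 sections. The lipid and foreign-body macrophage list had 7 of 11 rise, 9 alone (camera adjusted p = 6.76e-05, adjusted p = 0.237 with an estimated correlation), with Trem2 (10.9 to 24.2 CPM) and Spp1 (9.88 to 20.2 CPM). In the complement list 6 of 10 rose, 8 alone (camera adjusted p = 7.73e-06, adjusted p = 0.237 with an estimated correlation), C4b among them (99 to 243 CPM), and in the fibrillar collagen list 9 of 22, 17 alone (camera adjusted p = 4.89e-08, adjusted p = 0.296 with an estimated correlation). The macrophage, complement and collagen lists were also higher in fibre-poor spots. Whether mixing with that tissue contributed to their rise at the border was not tested. The macrophage ratio was 0.020 in 2-week replicate 2. Thrsp (13.2 to 47.8 CPM) and Scd (138 to 318 CPM), genes of fat synthesis, Clrn1, Ppp1r14c, Emb, Slc51a and Cst7 were the other largest rises, with log2 fold changes between 1.36 and 1.89. Vegfa, the vessel growth factor, fell from 98.9 to 52.6 CPM in 5 of 6 sections.

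At the border, 342 genes passed in the shared batch alone. The count was 509 without 8-week replicate 1, 386 without 8-week replicate 2, 440 without 2-week replicate 1 and 469 without 2-week replicate 3, and 333 with the boundary set in each section.

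**Figure D5:**
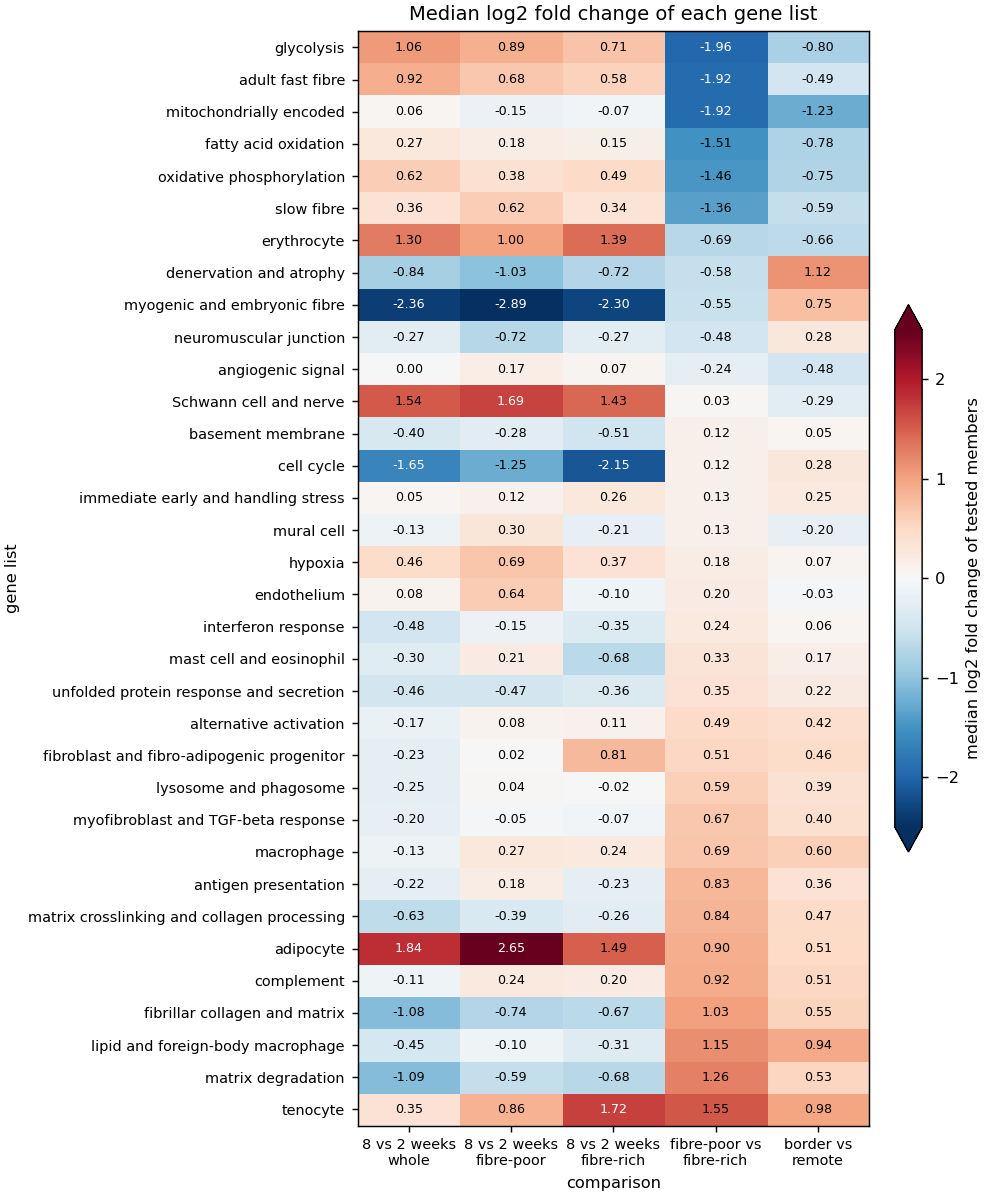
Median log2 fold change of each gene list (vertical axis) in 5 comparisons (horizontal axis), with red for higher and blue for lower. The adipocyte list has a median of 2.65 in fibre-poor spots at 8 against 2 weeks, and the oxidative phosphorylation list of -1.46 in fibre-poor against fibre-rich spots.

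How strongly transcripts were patterned over each section was compared from the deposited Moran's I, which is near 0 for a random arrangement and near 1 where like neighbours like. Col1a1 and Col1a2 had the highest mean scores at 2 weeks (0.734 ± 0.080 and 0.662 ± 0.090, SD, n = 4), and Mt-co3, a mitochondrial oxidase subunit, and Mt-cyb at 8 weeks (0.592 ± 0.061 and 0.508 ± 0.066, SD, n = 2). Of 42 lists, 35 had a lower median score at 8 weeks, with a median difference of -0.0121. With only genes detected in at least 10% of spots, 19 of 26 lists were lower, with a median difference of -0.0313. The 8-week sections were also shallower, with a median of 1569 and 2396 UMIs per spot against 2894 to 6862 at 2 weeks. Whether depth lowered the scores was not tested. When the table of each section was left out in turn, 26 to 37 lists were lower and the median difference was -0.00633 to -0.0199, with both extremes where a table filed under 2-week replicate 1 or 2 was left out. The myogenic and embryonic list had 0.150 ± 0.049 at 2 weeks (SD, n = 4) and 0.0295 ± 0.0010 at 8 weeks (SD, n = 2), and the oxidative phosphorylation list 0.180 ± 0.027 and 0.0543 ± 0.025. These lists, cell cycle, fatty acid oxidation and the unfolded protein response reached the smallest exact permutation p of 0.0667 (adjusted p = 0.467, two-sided). Over whole sections, expression of the myogenic and cell cycle lists was also lower at 8 weeks by median log2 fold change. That of the oxidative phosphorylation list was higher. Whether expression level moved the scores was not tested. The design of 4 against 2 sections could not reach the threshold, and 0 lists passed it. Within the shared batch 36 of 42 lists were lower at 8 weeks, with a median difference of -0.0196 and a smallest exact permutation p of 0.333 from 6 splits.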

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

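The test for a mislabelled section and the dilution test of mitochondrially encoded genes were chosen after the results were seen, as was the comparison within remote spots that another test uses, and the remaining tests of explanations in this part before. Of 58 values tested for a section far from the others among the 4 sections at 2 weeks, 3 were past the critical value, and chance gives about 1 in 20. All 3 were in 2-week replicate 1. Mitochondrial genes made up 10.5% of its UMIs in fibre-poor spots, Actc1 stood at 1294 CPM in its fibre-poor spots, and S100b at 5.96 CPM in its fibre-rich spots. Of these, the first and second were the highest and the third was the lowest of the 4 sections.

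2-week replicate 1 also differed from the other 2-week sections in its overall profile. Over whole sections its mean correlation of log2 CPM, across genes, was lower with the other 2-week than with the 8-week sections, by a difference of -0.00804, whereas it was higher with their own week in the other 2-week sections. A wrong week label is argued against, since the myogenic and embryonic list lay a median of 2.17 log2 units above the 8-week mean in its fibre-rich spots, with 15 of 16 members higher, and only 0.57 above the other 2-week sections. Its tissue composition may account for the difference, since in fibre-rich spots alone the correlation with its own week was higher by 0.00591, inside the range of the other 2-week sections from 0.00447 to 0.0238. That margin is small, and whether the section was cut at another depth of the defect or the animal healed faster stays open and was not tested.

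The fall of embryonic, myogenic and cell cycle genes in fibre-rich spots between 2 and 8 weeks had 18 passing members. In remote fibre-rich spots the members' median log2 fold change was 1.11 times that in all fibre-rich spots (quartiles of the members 0.988 to 1.15). Of 17 members tested there, 15 passed. This cannot decide whether fibre-poor tissue inside the spots was a cause, since the compared spots largely overlap. Remote spots were 2241 of 2509 and 1137 of 1586 fibre-rich spots in 8-week replicates 1 and 2. They were 1063 of 1507 and 80 of 238 in 2-week replicates 1 and 2. Distance from a patch also does not measure fibre-poor tissue within a spot. After thinning to equal totals, 12 of the 18 members were still tested. Their median was 1.04 times its value before (quartiles 0.981 to 1.13), and 11 passed. That argues against depth for those 12 members. For the members no longer tested after thinning, depth stays open. A difference between the labelled batches was not tested separately, since the fall was estimated within the shared batch, and unlabelled differences between those sections stay open. Time after treatment remains as a hypothesis consistent with these values, and with 2 animals at 8 weeks and no untreated muscle it may also include differences between animals.

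Oxidative genes were lower in border than in remote fibre-rich spots, the oxidative phosphorylation list in 5 of 6 sections, with a median log2 ratio of 0.0899 in 2-week replicate 2. The oxidative phosphorylation list fell by a median of 0.75 on the log2 scale and the fibre genes that set the classes by 0.52. The difference was -0.227 (mean over sections -0.22 ± 0.29, SD, n = 6, lower in 5 of 6 sections). A difference this small was predicted under dilution of fibre RNA by neighbouring tissue. It cannot decide whether dilution took part, since the zones were set by the share of these fibre genes in spots and their neighbours. The mitochondrially encoded list fell by a median of 1.23, below the fibre genes by -0.706 (mean over sections -0.712 ± 0.41, SD, n = 6, lower in 5 of 6 sections). That difference cannot decide whether dilution was the whole cause. Border spots had to reach the boundary of fibre share, which limits the fall of the fibre genes but not that of mitochondrially encoded genes. What lowered the mitochondrially encoded genes stays open. Whether border fibres were of another type cannot be told apart from dilution. The slow list lay below the fast list by a median difference of -0.106 in the fit, and by -0.53 ± 0.94 (SD, n = 6) as a mean over sections, a spread larger than either value, with 4 of 6 sections lower. The myogenic list had 6 members lower in fibre-poor spots and 8 members higher at the border, and whether mixing with fibre-poor tissue contributed to that rise was not tested.

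The cartilage and bone list, with 4 tested members of 12, was higher in fibre-poor spots at 2 weeks and lower at 8 weeks. Its median log2 ratio of fibre-poor to fibre-rich spots was 1.03 ± 0.22 at 2 weeks (SD, n = 4) and -0.263 ± 0.015 at 8 weeks (SD, n = 2), positive in 4 of 4 and negative in 2 of 2 sections. At 8 weeks Acan was at 0 CPM in both classes and Runx2, Sox9 and Alpl at 1.26 to 11.4 CPM, so the sign at 8 weeks rests on few UMIs. This difference was not tested.

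Spots outside tissue, used only in the alternative with every barcode, held UMIs in every section, with no control to compare them with. They made up 14.1% and 10.4% of all UMIs in 8-week replicates 1 and 2, and 6.97%, 6.27%, 21.3% and 23.3% in 2-week replicates 1 to 4, with 95% Wilson intervals at most 0.0528 points wide.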

How the results depend on the processing

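The alternative with remote spots alone was chosen after the data were seen, and all others before. The contrast of fibre-poor with fibre-rich spots stayed within 1.5 times its count in every alternative run, from 3456 to 5401 genes. The share of fibre-poor spots was lower at 8 weeks in every alternative, by -25.0 points with the boundary set in each section to -63.3 without 2-week replicate 1, and no list passed for Moran's I in any. The counts of genes at 8 against 2 weeks depended on the sections and settings. In whole sections 116 genes passed with no batch term, 0 in the shared batch only (1351 at an unadjusted p under 0.05 by edgeR), 358 with DESeq2 and 498 with no filter on low counts, and 0 to 2313 when a section was left out. In fibre-poor spots 295 passed with no batch term, 332 with DESeq2, 935 with no filter, 0 with the boundary set in each section (1778 at an unadjusted p under 0.05), 92 with spots near the boundary left out, and 0 to 596 when a section was left out. In fibre-rich spots 1266 passed with no filter, 183 after thinning, 72 with the boundary set in each section, 456 in remote spots alone, and 76 to 543 when a section was left out. For the interaction 43 passed with no filter, 4 with spots near the boundary left out, and 0 to 162 when a section was left out. At the border 424 passed after thinning, 342 in the shared batch, 333 with the boundary set in each section, 378 with spots near it left out, and 386 to 1177 when a section was left out. Lists passing went from 18, 15, 17, 20 and 21 to 0 with an estimated correlation, and stayed at 16 to 24, 10 to 21, 15 to 20, 18 to 21 and 20 to 22 when a section was left out, in the order whole, fibre-poor, fibre-rich, class and border. Where 8-week sections are left out, the lone remaining section is assumed to vary like the others, and the cause was not tested for any of these moves beyond fewer samples or reads.

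With the replicate number as a block in place of batch, 95 genes passed in fibre-poor and 1045 in fibre-rich spots. The labels do not give the numbers as a pairing. Deviations of sections with the same number had a correlation across genes of -0.061, -0.171 and 0.094 in whole sections, fibre-poor and fibre-rich spots. Each value rests on a single pair of deviations, so it cannot decide whether the numbers are a pairing.

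Over 407 named genes and comparisons, 5838 alternative values kept their side of the threshold, 504 no longer passed, 405 newly passed and 2 reversed. A reversal was counted only where the main or the alternative value passed. Changes of direction between values that did not pass are among the 5838. At the border with the boundary set in each section, Chad had a log2 fold change of -0.070 and Tnnt1 of 0.17, and the cause was not tested. Recovery of planted changes of 1 on the log2 scale was lowest in fibre-poor spots, at 5.10%, and the cause was not tested.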

Other observations

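No test in this part was chosen after the result was seen. Several lists that the comparisons of time did not describe passed camera with its preset correlation and none with an estimated one. The erythrocyte list had 3 tested members in fibre-rich spots, none of which passed over all genes while 3 rose at 8 weeks when adjusted over the list alone (median log2 fold change 1.39, camera adjusted p = 0.0325, adjusted p = 0.685 with an estimated correlation). In fibre-poor spots the denervation and atrophy list had a median of -1.03, with 0 of 12 members passing and 5 falling when adjusted over the list alone (camera adjusted p = 0.00866, adjusted p = 0.739 with an estimated correlation). The neuromuscular junction list there had a median of -0.72, with 1 of 11 members falling when adjusted over the list alone (camera adjusted p = 0.0463, adjusted p = 0.739 with an estimated correlation).

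Between the classes of spots, genes of oxygen sensing and vessel growth went both ways. Vegfa fell in fibre-poor spots from 95.7 to 42.7 CPM and Vegfb from 87.7 to 49.4 CPM, each lower in 6 of 6 sections, while Hif1a, the oxygen-regulated transcription factor, rose from 38 to 80.8 CPM in 6 of 6 sections. The angiogenic list had 2 members rise and 2 fall of 11, the same when adjusted over the list alone (camera adjusted p = 0.679). In the alternative activation list 7 of 10 members rose, 7 alone (camera adjusted p = 0.00925, adjusted p = 0.349 with an estimated correlation), with the growth factor Igf1 (45.5 to 113 CPM) and the scavenger receptor Stab1 (40.9 to 73 CPM). In the classical inflammation list 3 of 7 rose, 4 alone (camera adjusted p = 0.111), with the chemokines Ccl3 (3.19 to 10.6 CPM) and Ccl2 (14.5 to 27.4 CPM) in 6 of 6 sections. Whether these lists differed from each other was not tested.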
